A study of Mus musculus with 6 samples.

How the data were processed

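Total RNA from heads of mouse embryos at embryonic day 9.5 was amplified, labelled with Cy3 and hybridised to Agilent one-colour arrays, per the labels' protocols, with 3 wild type and 3 Arid3b-null samples of 4 pooled embryos each. Nothing says whether pools of 1 group came from separate litters, so p-values measure the spread between these pools. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited scanner files give 1 intensity per spot after background subtraction and spatial detrending (the processed signal), the raw median intensity of the spot and of its background, and flags for spots well above background, saturated or outlying, per the file headers. A value table deposited by the authors holds log2 values for 24181 rows, of which 24158 match non-control probes. Its column medians are 6.76 to 6.77, its columns correlate with the log2 scanner signal of their own array at 0.999 or more across probes, and their quantiles are nearly alike; how the table was made is not given in the sources used here, and its exact scaling stays unknown.

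The main values are log2 of the processed signal minus the 75th percentile of it on the same array over non-control spots. Control spots and outlier-flagged spots (84 to 156 per array) were left out and spots of a probe averaged. Of 39429 probes, 26418 were named with 1 gene symbol each through a RefSeq accession, 0 with several, and 13011 had no symbol in the table used. The table is of assembly GRCm38 and served only for names and gene order, since the files analysed here give no probe coordinates; no coordinates are printed. Probes well above background on all 3 arrays of at least 1 group and measured on at least 5 arrays were kept (26288), and the probe with the highest mean stood for each of 14902 genes. Of 158 genes named under the rule below besides Arid3b, 24 had another kept probe; among those that changed, no other probe had the opposite sign, though sizes differed.

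Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). A gene not well above background on any array of 1 group has only a bound there: the mean of the bright group was set against the dim group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background, and the fold is written as at least N-fold, a bound for the processed signal and not for other background corrections, with the adjusted p of the fit. Where another probe of the gene was well above background in the dim group, as for Lox, no bound is given. Gene lists (33, with 636 entries, 8 updated from older symbols and 2 unmatched) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Named genes are Arid3b, the 12 largest rises and 12 largest falls among changed genes whose groups do not overlap and whose symbol is not a clone name, up to 4 members per list with the smallest p, and in lists of other tissues and sex genes the 3 brightest. The lists, this rule, the tests and most alternatives were fixed before the data were examined; not every gene of the rule is named, and genes outside the rule that are named were chosen after their values were seen.

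Each slide and each scan held the wild type and null array of 1 replicate number, so the slide block and the replicate block are 1 model, and list medians are also given within each slide. Alternatives were quantile normalization, median centring, the deposited value table, other filters on dim probes, other rules for the probes of a gene, an intensity trend with robust variance, array weights, the slide block, other thresholds and leaving out each array. Normexp was planned on mean signals, which the scanner files analysed here do not hold, and was run on median signals with an offset of 50. A test of genes within a distance of Arid3b was planned for files with probe coordinates; gene order was used in its place. Both substitutes were chosen after seeing the data. The steps were tested on simulated data for the null against wild type comparison with 14894 genes of the observed means and spreads: 3 of 50 were recovered at 1.5-fold, 20 of 50 at 2-fold, 43 of 50 at 4-fold and 47 of 50 at 8-fold, with 4 calls among the 14694 unchanged genes. Far fewer genes were changed in this simulation than were called in the data, so a smaller unadjusted p was needed to pass. The recovery counts therefore do not carry over to the data. In a second simulation with 1 list shifted, camera called 2 of 33 lists, the shifted list among them. Both simulations drew the genes independently, so they cannot check the preset correlation of camera.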

Results

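RNA was measured in heads of mouse embryos at embryonic day 9.5, dissected to include the head and the first branchial arch, which gives rise to the jaws. The series compared 3 wild type samples with 3 samples from embryos null for Arid3b, a DNA-binding protein with an AT-rich interaction domain. Each sample was RNA pooled from 4 embryos and hybridised to 1 one-colour Agilent array. Between 67.9% and 70.3% of the non-control spots were well above background on each array, none was saturated, and the 75th percentile of the signal ran from 626 to 977. Correlations across genes were 0.977 to 0.986 among wild type arrays, 0.992 to 0.993 among null arrays and 0.965 to 0.975 between the groups, over genes that are not independent replicates. Each slide held the wild type and the null array of 1 replicate number, with every wild type array in position 1 and every null array in position 2, so position and genotype cannot be told apart. Values are log2 differences, null minus wild type, ± the standard error from limma, with n = 3 arrays per group; the number of arrays limits their precision.

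The comparison asks which genes differ between heads with and without Arid3b, and the targeted gene was examined first. Arid3b signal was lower on all 3 null arrays than on any wild type array. The brightest of its 3 probes fell from 2.45 ± 0.58 to 1.26 ± 0.19 (mean ± SD of log2 signal relative to the 75th percentile, n = 3), 2.28-fold lower (log2 difference -1.19 ± 0.29), with a limma adjusted p of 0.0266 (0.0177 with slide as a block). The difference within slides 1, 2 and 3 was -0.71, -1.20 and -1.66. Tested as single probes, the other 2 fell by 1.37 and 2.33 on the log2 scale, to 38.7% and 19.9% of the wild type signal, with adjusted p of 0.0224 and 7.59e-04. All 3 probes stayed well above background on all 6 arrays, and whether any lies in the deleted part of the gene is not given in the sources used here; a probe outside it would not check the labels. The call of the brightest probe was lost without null replicate 1, 2 or 3 (adjusted p of 0.0861, 0.0839 and 0.0690) and without the filter on dim probes (0.0599); over all its alternatives the adjusted p ran from 0.00378 to 0.0861.

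Across the genome, 3503 of 14902 genes changed at an adjusted p under 0.05 in limma, 1833 higher and 1670 lower in the null heads. Of these, 770 rose and 472 fell by at least 2-fold. The 12 largest rises that met the naming rule were led by Chac1, an enzyme that breaks down glutathione, which was 41.5-fold higher (log2 difference 5.38 ± 0.15). Eno2, the neuronal enolase of glycolysis, was 21.0-fold higher (log2 difference 4.39 ± 0.13), and Ndufa4l2, a mitochondrial protein induced by low oxygen, was 17.1-fold higher (log2 difference 4.09 ± 0.14). Ppp1r16b, Bhlhe40, Ndrg1, Car9 and Ier3 rose by 14.8, 13.1, 11.4, 10.5 and 10.1-fold. Hoxb8, well above background on 2 of 3 wild type arrays, rose by 3.35 ± 0.70 (adjusted p of 0.0161). Crx, Slc16a14 and Fut1 were not well above background in wild type heads and were at least 2.45-fold, 3.49-fold and 7.70-fold higher, with adjusted p of 9.20e-04, 0.00203 and 3.11e-04; normexp background correction, chosen after seeing the data, did not call Crx (log2 0.24) or Slc16a14 (log2 0.28). Normexp gave smaller log2 differences for Chac1 4.64, Ppp1r16b 2.64, Bhlhe40 2.34, Car9 2.43, Ier3 2.22, Fut1 0.66 and Hoxb8 0.67, so the bound of Fut1 holds for the processed signal alone. Ppp1r16b was 3.23 as the mean of its probes (2.57 on the other one), and Hoxb8 was 2.55 without wild type replicate 1. Hoxb8 lost its call without null replicate 1 (0.0647) and null replicate 3 (0.0658), the adjusted p given in parentheses.

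The largest falls held several developmental regulators. Lhx8, a homeodomain factor of the first arch, was 8.90-fold lower (log2 difference -3.15 ± 0.26), and Hand2, a basic helix-loop-helix factor of the arches and heart, was 6.70-fold lower (log2 difference -2.74 ± 0.29). Dbh, the enzyme that makes noradrenaline, was 8.50-fold lower (log2 difference -3.09 ± 0.16), and the gap junction gene Gja5 was 7.66-fold lower (log2 difference -2.94 ± 0.22). Cryge, a lens crystallin, was 6.23-fold lower (log2 difference -2.64 ± 0.25). Lhx4, a regulator of pituitary development, fell by 2.65 ± 0.15 on the log2 scale and was well above background on 2 of 3 null arrays; Nppc fell by 2.99 ± 0.70 and was well above background on 1. Its call was lost without the filter on dim probes and without wild type replicate 1 (0.0677), wild type replicate 2 (0.0595), null replicate 2 (0.0513) and null replicate 3 (0.0886), the adjusted p given in parentheses. Gykl1, Btla, Nr0b1, Ifi202b and Saa2 were not well above background in null heads and were at least 2.90, 2.36, 5.16, 2.50 and 4.52-fold lower, with adjusted p of 0.00262, 0.00215, 8.14e-04, 0.00466 and 0.00300. Btla (log2 -0.45) and Ifi202b (log2 -0.46) were not called with normexp. The differences of the other falls were also smaller with normexp, at log2 Lhx8 -2.17, Hand2 -2.10, Dbh -1.27, Gja5 -1.65, Cryge -1.60, Lhx4 -0.85, Nppc -0.71, Gykl1 -0.56, Nr0b1 -0.67 and Saa2 -0.68, below the bounds given for the last 3. Nppc was -3.80 without null replicate 1 and -2.33 without null replicate 2.

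In all 3503 genes the 3 arrays of a group lay apart from those of the other; this held for 42.4% of all tested genes, where chance gives 10%. With the slide as a block 3689 genes were called, 1927 higher and 1762 lower, including 3170 of the 3503. The sign was the same within each of the 3 slides for 3501 of the 3503. Groups that lie apart must share a sign on every slide where both arrays gave a value, so this count is no further evidence. A kept gene could lack a value on 1 array. A single slide holds 1 array per group and allows no test. The count fell to 2136 without wild type replicate 1, to 2170 without wild type replicate 2, and to 1513, 1867 and 1859 without null replicates 1, 2 and 3. It rose to 5197 without wild type replicate 3, with 2662 genes lower. It was 2269 without the filter on dim probes and 6681 with array weights.

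**Figure D1:**
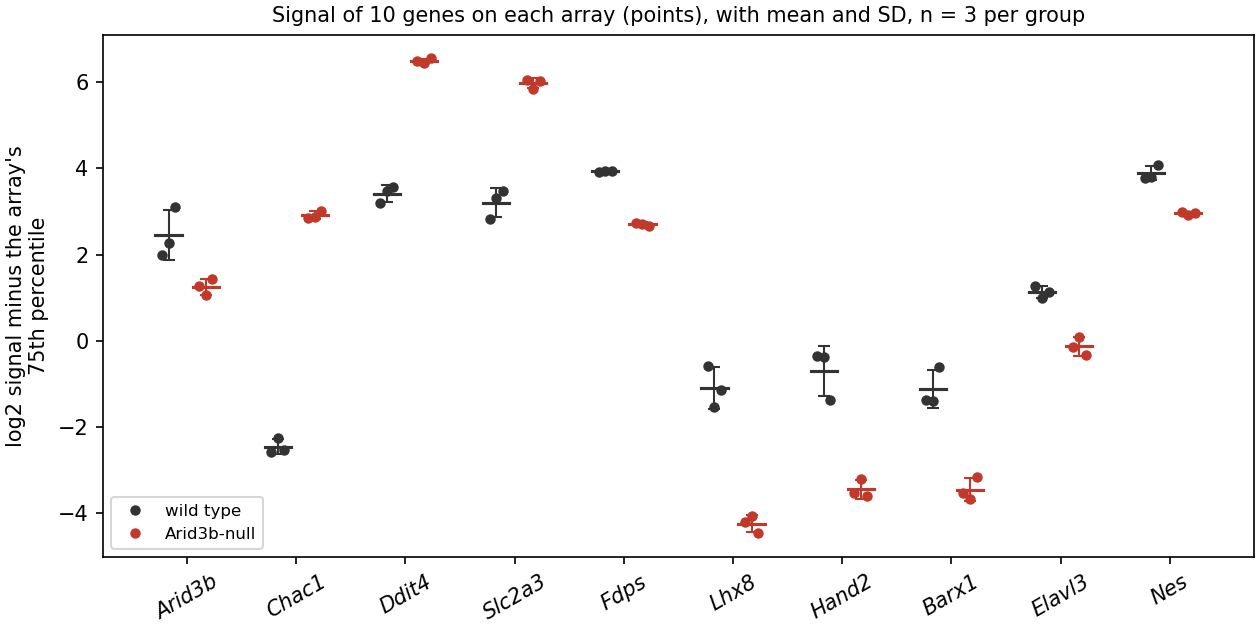
Log2 signal minus the array's 75th percentile (vertical axis) for 10 genes (horizontal axis), with 1 point per array, bars at the mean and whiskers of 1 SD, for 3 wild type (black) and 3 Arid3b-null arrays (red). Chac1, Ddit4 and Slc2a3 lie higher and the other 7 genes lower on all 3 null arrays; levels of different genes are not comparable.

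Most measured genes of the list of low oxygen and glycolysis were higher in null heads. Of 27 measured members, 21 rose and none fell (23 changed when adjusted over the list alone). The 6 that did not pass were Hk2 (1.05), Higd1a (0.43), Ldha (0.28), Eno1 (0.23), Gapdh (0.06) and Pfkfb4 (-0.13). Ddit4, an inhibitor of mTOR signalling, was 8.51-fold higher (log2 difference 3.09 ± 0.15), the glucose transporter gene Slc2a3 was 6.83-fold higher (log2 difference 2.77 ± 0.19), and Car9, a carbonic anhydrase used as a marker of hypoxia, was 10.5-fold higher (log2 difference 3.40 ± 0.15). P4ha1, a collagen prolyl hydroxylase, was 3.59-fold higher (log2 difference 1.84 ± 0.13). Hypoxia and glycolysis genes had a median of 1.68, with 1.77, 1.68 and 1.52 within slides 1, 2 and 3. For hypoxia and glycolysis genes camera gave an adjusted p of 8.67e-17, and 5.03e-15 with slide as a block; adjusted p = 0.117 with an estimated correlation. The 3 lists of other tissues that bear on oxygen supply gave these values: of 18 erythroid genes only Klf1 fell (-1.04 ± 0.24), of 16 heart genes only Tbx20 fell (-0.86 ± 0.14), and of 20 endothelial genes Esm1 (2.95 ± 0.19) and Apln (0.66 ± 0.12) rose. With slide as a block 2 heart genes, Myl3 (-1.36) among them, and 1 endothelial gene were called lower. Among named genes, array weights also called Cdh5, Myl3, Myl4, Tnni1 and Tnnc1 lower and Robo4 higher. Without wild type replicate 1, Cdh5, Myl3, Tnni1 and Tnnc1 were called lower too (limma adjusted p of 0.0128 to 0.0236). Tnni1 also passed with median centring (0.0476) and with an intensity trend and robust variance (0.0486). Cdh5 also passed with normexp (0.0434) and with that trend (0.0489). Klf1 lost its call without the filter on dim probes and without null replicate 1 (0.0804) and null replicate 3 (0.0828), Apln without null replicate 1 (0.0510), and Tbx20 with normexp (log2 -0.37). Car9 was at log2 2.43 with normexp.

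Targets of the integrated stress response, the program run by Atf4 when translation is restrained, were also higher: 14 of 19 rose and none fell (15 when adjusted over the list alone). Beside Chac1, Stc2 was 8.46-fold higher (log2 difference 3.08 ± 0.16), Trib3 was 8.21-fold higher (log2 difference 3.04 ± 0.20), and Ddit3, the factor known as CHOP, was 5.65-fold higher (log2 difference 2.50 ± 0.16). Stress response targets had a median of 1.29, with 1.32, 1.19 and 1.59 within slides 1, 2 and 3. For stress response targets camera gave an adjusted p of 2.19e-11, and 7.62e-11 with slide as a block; adjusted p = 0.0503 with an estimated correlation. Cholesterol synthesis genes moved the other way, with 14 of 20 lower and none higher (16 when adjusted over the list alone). Msmo1 was 2.98-fold lower (log2 difference -1.57 ± 0.14), and Hmgcs1 and Fdps fell by 1.27 and 1.22. Cholesterol synthesis genes had a median of -0.90, with -0.83, -0.99 and -0.96 within slides 1, 2 and 3. For cholesterol synthesis genes camera gave an adjusted p of 8.32e-08, and 5.33e-08 with slide as a block; adjusted p = 0.0534 with an estimated correlation.

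Of 25 p53 targets, 11 rose and none fell (14 when adjusted over the list alone). With slide as a block 10 rose and 1 fell. Members that did not pass included Mdm2 (-0.04), Bax (-0.02), Trp53inp1 (-0.01) and Ccng1 (0.70). Sesn2, which also stands on the stress response list, was 4.14-fold higher (log2 difference 2.05 ± 0.21), and Pmaip1, the proapoptotic gene Noxa, was 2.46-fold higher (log2 difference 1.30 ± 0.16). Gdf15 was not well above background in wild type heads and was at least 4.67-fold higher (adjusted p of 0.00378; not called with normexp, log2 0.41). P53 targets had a median of 0.45, with 0.31, 0.64 and 0.64 within slides 1, 2 and 3. For p53 targets camera gave an adjusted p of 0.00179, and 0.00240 with slide as a block; adjusted p = 0.453 with an estimated correlation. Among 20 apoptosis regulators 3 rose and 2 fell (9 changed when adjusted over the list alone), with Hrk, a BH3-only gene, 9.37-fold higher (log2 difference 3.23 ± 0.16), and Bad and Cycs lower at -0.97 ± 0.14 and -1.14 ± 0.21. Their median was -0.13 and its camera adjusted p was 0.749. Of 28 cell cycle genes none rose and 5 fell (5 when adjusted over the list alone), among them Tyms (-1.51 ± 0.17), Rrm2 (-1.21 ± 0.14) and Ccne1 (-1.22 ± 0.15), which act in nucleotide supply and entry into S phase; the list median was -0.18 and its adjusted p 0.0920. Of 18 immediate early and heat shock genes 6 rose and 1 fell (8 when adjusted over the list alone): Ier3, Nr4a1 (1.26 ± 0.15) and Atf3 (1.77 ± 0.24) rose and the chaperone gene Hsph1 fell (-1.46 ± 0.16), with a list median of 0.09 and an adjusted p of 0.429. With normexp the log2 differences of Hrk 1.75 and Ier3 2.22 were smaller.

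Genes that pattern the branchial arches changed in both directions: 8 of 25 fell and 4 rose (13 changed when adjusted over the list alone). Besides Lhx8 and Hand2, Barx1, a factor of molar-forming arch mesenchyme, was 5.05-fold lower (log2 difference -2.34 ± 0.25). The arch median was -0.25, with -0.12, -0.18 and -0.45 within slides 1, 2 and 3, and the list was not called (camera adjusted p of 0.0772, 0.453 with an estimated correlation). It was called after quantile normalization and in the deposited value table (adjusted p of 0.0398 and 0.0382), and without wild type replicate 1 or 2 (0.0472 and 0.0360), with 0.0360 to 0.225 over its alternatives. The second probes of Lhx6 and Prrx1 disagreed with the brightest, at -1.69 against -0.08 and at 0.68 against -0.85. Of 20 neural crest genes 5 rose and none fell (5 when adjusted over the list alone). Tfap2a, an early crest regulator, was 1.96-fold higher (log2 difference 0.97 ± 0.13), and Cdh6, a cadherin of early crest, was 2.41-fold higher (log2 difference 1.27 ± 0.16). Neural crest genes had a median of 0.30, with 0.47, 0.43 and 0.32 within slides 1, 2 and 3. For neural crest genes camera gave an adjusted p of 0.00595, and 0.00380 with slide as a block; adjusted p = 0.194 with an estimated correlation. Among 18 genes of cranial mesenchyme matrix 5 rose and 1 fell (6 when adjusted over the list alone), with the matrix genes Dcn (1.04 ± 0.17) and Col6a1 (1.03 ± 0.15) higher. Matrix genes had a median of 0.28, with 0.28, 0.36 and 0.27 within slides 1, 2 and 3. For matrix genes camera gave an adjusted p of 0.0416, and 0.0355 with slide as a block; adjusted p = 0.462 with an estimated correlation. The matrix call was lost with array weights (0.0695), on probes above background on all 6 arrays (0.0766), and without wild type replicate 3 (0.116) or null replicate 1 or 2 (0.0622 and 0.0837), with 0.0157 to 0.116 over its alternatives. Of 12 head mesoderm genes Cyp26c1 rose (1.84 ± 0.23) and Lhx2 fell (-1.08 ± 0.19; 2 changed when adjusted over the list alone), with a median of -0.08 and an adjusted p of 0.844. Smaller log2 differences came with normexp for Lhx8 -2.17, Hand2 -2.10, Barx1 -1.59 and Cyp26c1 0.99.

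Some markers of neurons and of neural progenitors fell, and most did not pass the test. Of 25 genes of neuronal differentiation 8 fell and 1 rose (10 when adjusted over the list alone). The early neuronal RNA-binding gene Elavl3 was 2.40-fold lower (log2 difference -1.27 ± 0.16), the helix-loop-helix gene Nhlh2 was 2.60-fold lower (log2 difference -1.38 ± 0.21), and Chga, of secretory granules, was 1.81-fold lower (log2 difference -0.86 ± 0.14). Neuronal genes had a median of -0.50, with -0.36, -0.30 and -0.90 within slides 1, 2 and 3. For neuronal genes camera gave an adjusted p of 0.00179, and 0.00258 with slide as a block; adjusted p = 0.566 with an estimated correlation. Of 15 neural progenitor genes 5 fell and none rose (5 when adjusted over the list alone), with the radial glial gene Fabp7 2.95-fold lower (log2 difference -1.56 ± 0.21) and the intermediate filament gene Nes 1.91-fold lower (log2 difference -0.93 ± 0.14). Progenitor genes had a median of -0.28, with -0.44, -0.12 and -0.63 within slides 1, 2 and 3. For progenitor genes camera gave an adjusted p of 0.0354, and 0.0423 with slide as a block; adjusted p = 0.462 with an estimated correlation. Both calls were lost with array weights (adjusted p of 0.0695 and 0.144) and without wild type replicate 3 (0.0533 and 0.116), and that of progenitors also without null replicate 2 or 3 (0.0556 and 0.0581). The adjusted p was 4.25e-05 to 0.0695 over its alternatives for neuronal and 0.0160 to 0.144 over its alternatives for progenitor genes.

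Regional genes of the brain changed in both directions. Of 29 forebrain and midbrain genes 6 fell and 4 rose (14 when adjusted over the list alone): Nkx2-1 of the ventral forebrain (-1.20 ± 0.22), Lhx2 (-1.08 ± 0.19) and the eye and pituitary gene Six6 (-0.93 ± 0.16) fell, and Wnt1 of the midbrain (1.32 ± 0.17, and 2.29 on its other probe) rose. The forebrain and midbrain median was 0.09 while its mean and its test pointed down (mean -0.03, adjusted p of 0.953). Of 15 hindbrain genes 4 rose and 2 fell (8 when adjusted over the list alone). Egr2, a rhombomere gene, rose by 1.15 ± 0.22 but lost its call without null replicate 1 (0.0541) and null replicate 3 (0.0513). The hindbrain median was 0.12, its mean -0.06 and its adjusted p 0.844. Among 19 placode and lens genes 4 fell and 2 rose (10 when adjusted over the list alone), with Oc90 of the otic vesicle 5.66-fold lower (log2 difference -2.50 ± 0.36) and Hmx2 and Hmx3 higher by 1.13 ± 0.16 and 1.05 ± 0.18; the median was -0.09 and the adjusted p 0.749. Of 20 surface ectoderm genes 2 rose and Krt15 fell (-1.58 ± 0.28; 3 when adjusted over the list alone; median 0.35, adjusted p of 0.341), a list called without wild type replicate 2 (adjusted p of 0.0311; 0.0311 to 0.749 over its alternatives; adjusted p = 0.736 with an estimated correlation). Of 13 pharyngeal endoderm genes 3 rose, Sox17 among them (1.23 ± 0.14), and 1 fell (7 when adjusted over the list alone). That list's median was -0.04, its mean 0.16 and its test upward, with an adjusted p of 0.552. Normexp moved Oc90 -1.44 and Hmx2 0.50 on the log2 scale.

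Among signalling lists, 7 of 18 Bmp targets and ligands rose and 2 fell (9 when adjusted over the list alone). Those that rose were the ligand genes Bmp2, Bmp4, Bmp5 and Bmp7, with Grem1, Msx2 and Smad9, the last not called with normexp. Id1 (0.49), Id2 (0.05), Id3 (-0.28), Smad6 (0.37) and Smad7 (0.38) did not pass. Bmp2 was 2.92-fold higher (log2 difference 1.55 ± 0.16) and the Bmp antagonist gene Grem1 2.15-fold higher (log2 difference 1.11 ± 0.14), while Id4, a Bmp-induced inhibitor of helix-loop-helix factors, was 4.16-fold lower (log2 difference -2.06 ± 0.30). Bmp genes had a median of 0.42, with 0.37, 0.47 and 0.48 within slides 1, 2 and 3. For Bmp genes camera gave an adjusted p of 0.0354, and 0.0226 with slide as a block; adjusted p = 0.517 with an estimated correlation. The call was lost in the deposited value table (adjusted p of 0.0632), with array weights (0.0700) and without wild type replicate 3 or null replicate 2 (0.116 and 0.0565), with 0.0166 to 0.116 over its alternatives. Of 17 Wnt targets 6 rose and 1 fell (10 when adjusted over the list alone): Wif1 (1.95 ± 0.15), Rnf43 (1.19 ± 0.17) and Sp5 (0.86 ± 0.12) were higher and Ccnd1 lower (-1.20 ± 0.13), with a median of 0.51 and an adjusted p of 0.0772; the list was called with normexp (0.0286) and without the filter on dim probes (0.0268), with 0.0268 to 0.162 over its alternatives. For Wnt targets adjusted p = 0.427 with an estimated correlation. Of 15 genes of the Fgf list 3 rose (3 when adjusted over the list alone): the ligand genes Fgf8 (0.65) and Fgf15 (1.06 ± 0.24), and Flrt3 (0.67). Fgf15 lost its call without wild type replicate 1 (0.0641), wild type replicate 2 (0.0505) and null replicate 1 (0.0676). Fgf8 and Flrt3 lost theirs in 5 and 6 settings. The targets Dusp6 (0.32), Spry1 (0.35), Spry2 (0.05), Etv4 (-0.07) and Etv5 (-0.14) did not pass. The Fgf median was 0.32 and the adjusted p 0.0721, or 0.0423 with slide as a block. This list was also called with normexp (0.0286), quantile normalization (0.0392) and no filter on dim probes (0.0268), and without wild type replicate 1 (0.0353) or null replicate 3 (0.0382), with 0.0268 to 0.144 over its alternatives. For Fgf targets adjusted p = 0.517 with an estimated correlation, and 0.521 with that and the slide block. In the retinoic acid list 4 of 15 rose and 4 fell (9 when adjusted over the list alone): Rbp4 (1.72 ± 0.20), Cyp26c1 and Rarb (1.57 ± 0.14) were higher and the retinal dehydrogenase gene Aldh1a1 lower (-1.70 ± 0.19). Its median was -0.03, its mean 0.07 and its adjusted p 0.757. Of 15 Notch genes Heyl fell most (-2.61 ± 0.14), 3 fell in all and 2 rose (5 when adjusted over the list alone; median -0.0018, adjusted p of 0.562). Of 14 Hedgehog genes 3 fell and 2 rose (5 when adjusted over the list alone), with a median of 0.11, a mean of -0.06 and an adjusted p of 0.966; Foxf1, not well above background in null heads, was at least 2.61-fold lower (adjusted p of 0.00209; not called with normexp, log2 -0.37). The log2 differences with normexp were Wif1 0.999, Cyp26c1 0.99 and Heyl -1.26.

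Markers of other tissues that a head dissection can hold were examined in the same way. The erythroid list had a median of -0.14 (adjusted p of 0.562; 0 changed when adjusted over the list alone), and its brightest genes, the globins Hbb-y, Hbb-bh1 and Hba-x, differed by -0.07 ± 0.27, -0.16 ± 0.32 and 0.15 ± 0.33, none past the threshold. Of 12 macrophage and leukocyte genes 4 fell and 1 rose (6 when adjusted over the list alone): Tyrobp was lower (-1.35 ± 0.17) in every setting, the other 4 calls were each lost in 5 or more settings, and Csf1r (-0.25 ± 0.42, with 0.34 and -0.36 on its other probes) and Fcer1g (-0.38 ± 0.16) did not pass. Tyrobp was at log2 -0.70 with normexp. The leukocyte median was -0.31 and its adjusted p 0.122, or 0.0209 without wild type replicate 2 (0.0209 to 0.490 over its alternatives; adjusted p = 0.710 with an estimated correlation). The heart list had a median of -0.21 (0.30, -0.86 and -0.30 within slides 1, 2 and 3; adjusted p of 0.612; 1 changed when adjusted over the list alone), and its bright genes Actc1, Myh7 and Myl4 differed by 0.24 ± 0.33, -0.30 ± 0.38 and -1.29 ± 0.83. Myl4 was -2.03 without wild type replicate 1, -0.22 without wild type replicate 2, and -2.38 and called with array weights (adjusted p of 0.0468). The endothelial list had a median of 0.13 (adjusted p of 0.438; 2 when adjusted over the list alone). Of 13 somite and trunk genes 5 rose and 1 fell (6 when adjusted over the list alone; median 0.13, adjusted p of 0.214): Tbx6 rose (1.90 ± 0.15), though its other probe differed by 0.08, and Hoxb5 and Hoxb7, not well above background in wild type heads, were at least 4.34-fold and 2.47-fold higher (adjusted p of 0.0179 and 0.0163), while Tcf15 differed by 0.13 ± 0.15. Other posterior Hox genes on the list did not pass, with Hoxb6 at -0.27 ± 0.47, Hoxa7 at -0.16 ± 0.29 and Hoxa9 at -0.27 ± 0.39. Meox1 was the gene that fell (-0.91), and Pax7 rose (0.85) but lost its call in 7 settings. Tbx6 was 0.99 as the mean of its probes, and Hoxb5 was 1.98 without wild type replicate 3 and 2.13 with array weights. Normexp did not call Hoxb5 (log2 0.31) or Hoxb7 (0.057), and Hoxb5 and Hoxb7 lost their calls without null replicate 1 (0.0672) and null replicate 3 (0.0692) and without null replicate 1 (0.0594) and null replicate 2 (0.0559).

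Of 10 yolk sac genes 3 rose and 3 fell (8 when adjusted over the list alone), with Rbp4 (1.72 ± 0.20) higher and Apom (-1.57 ± 0.17) lower, and the bright gene Apoa2 at 0.16 ± 0.16; the median was 0.19, the mean -0.01 and the adjusted p 0.749. Of 15 genes of earlier embryonic stages 2 rose and 2 fell, with T, the brachyury gene of early mesoderm, at 1.54 ± 0.29 (2 of 3 wild type arrays well above background) and Trh at -1.01 ± 0.20 (5 when adjusted over the list alone; median -0.02, adjusted p of 0.739); T was not called with normexp (log2 0.22), and the calls of the others, Lin28a and Fgf5, were lost in 9 and 8 settings. Among 13 genes of the AT-rich interaction family Kdm5b (0.80 ± 0.14) and Jarid2 (0.89 ± 0.21) rose beside the fall of Arid3b itself, Jarid2 losing its call in 5 settings (3 when adjusted over the list alone; median 0.08, adjusted p of 0.562). Apom was at log2 -0.63 with normexp. None of 5 sex chromosome genes passed in limma, over all genes or when adjusted over the list alone (0). Ddx3y, Eif2s3y and Kdm5d of the Y chromosome differed by 0.59 ± 0.19, 0.74 ± 0.25 and 1.32 ± 0.61, and Xist by -0.53 ± 0.31, in pools of embryos of unstated sex (median 0.59, adjusted p of 0.300). Array weights called Ddx3y, Eif2s3y and Kdm5d (adjusted p of 0.00759, 0.0105 and 0.00476). Ddx3y (0.0402) and Kdm5d (0.00386, log2 2.07) passed without wild type replicate 3, and Ddx3y (0.0423) and Eif2s3y (0.0292) without null replicate 3. Kdm5d was at log2 0.35 with normexp and 1.97 with array weights.

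In all, limma's camera called 9 of the 33 lists with its preset correlation of 0.01: 6 higher and 3 lower. None was called with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way without comparing them with other genes, called 17. The slide block called the same 9 and the Fgf list. Camera with the preset correlation called 5 without wild type replicate 3 and 5 with array weights.

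**Figure D2:**
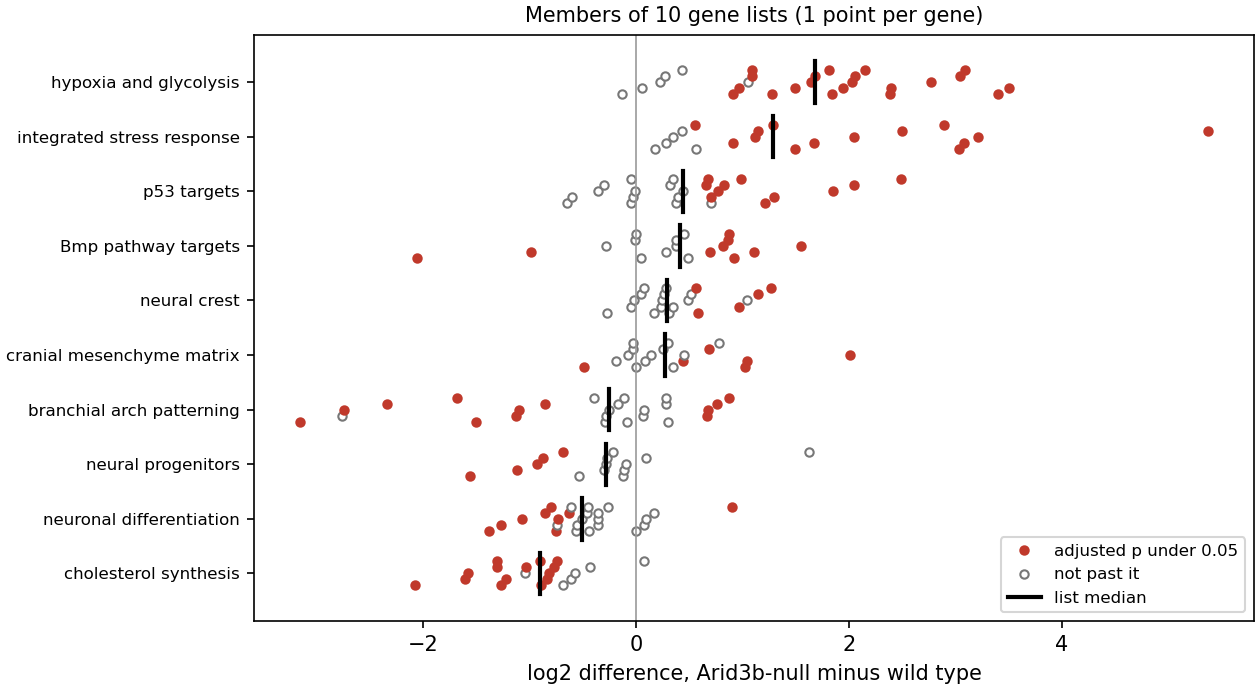
Log2 difference, null minus wild type (horizontal axis), of each measured gene in the 9 lists called by camera and in the branchial arch list (rows), with 1 point per gene, filled where the adjusted p was under 0.05, and a black bar at the list median. The medians run from 1.68 for hypoxia and glycolysis to -0.90 for cholesterol synthesis; the arch list spreads from Lhx8 at -3.15 to Msx2 at 0.87.

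Genes next to Arid3b were compared with the rest, since a targeted allele carries linked DNA of its strain of origin. By gene order, 12 of the 50 nearest measured genes (25 on each side) changed, or 24.0% against 23.5% of the other genes (2-sided Fisher's exact p = 0.869). Of these, 11 were higher and 1 lower. Compared with the directions of the other changed genes, this gave a 2-sided Fisher's exact p of 0.00690, 0.0201 when adjusted over 3 overlapping windows, in a test chosen after the directions were seen. The strain backgrounds are not given in the sources used here.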

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

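The tests of explanations in this part, the gene sets in them and the outcomes to expect of other splits were set after the results were seen. The bound for the somite genes was changed after their value was known; under the first bound they would have counted against trunk tissue. The arch explanation was likewise narrowed to an equal loss. Among the 6642 kept probes without a gene symbol, tested with the others as single probes, 905 (13.6%) passed an adjusted p of 0.05 in limma, 418 higher and 487 lower in null heads; they are a signal in data that the comparisons of genes do not use.

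The count of 3503 changed genes was set against the 10 ways of splitting the 6 arrays into 3 and 3. Only the real split gave as many (1 of 10), and the highest of the others was 0 in limma (69 to 2459 genes at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05. For the 9 lists called, 5 of the 10 splits, the real one included, gave as many, with 11 the highest of the others, and the splits are again too few to reach a share under 0.05. Each of the other splits sets 2 arrays of 1 group and 1 of the other against the reverse. It so keeps part of the group difference and puts the rest into the spread within its groups, and neither its genes nor its lists are counts from unchanged arrays. The hypoxia list itself had a median of 1.68 in the real split and of at most 0.66 in the others, where its camera adjusted p still fell as low as 1.59e-06.

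The first pattern is the rise of the hypoxia list in null heads. A difference between slides or scans falls on both groups alike, since each held 1 array of each group, so the design argues against it. The list was higher within each slide (lowest median 1.52), with a blocked camera adjusted p of 5.03e-15. In the 21 of 27 members that rose, the groups lay apart. The medians within slides therefore had to be positive and add no evidence. Fewer red blood cells in the null heads may limit oxygen, but the mean difference of 4 globin genes was -0.071 with a 95% interval of -0.99 to 0.84, too wide to decide. A longer time between dissection and lysis of the null heads could act on the same genes. The mean difference of 7 immediate early genes, none of which passed, was 0.096 (95% interval -0.54 to 0.73), which leaves it open. This set leaves out Ier3, Nr4a1, Atf3, Ccn1 (1.13) and Ccn2 (0.65), which all rose. Its mean near 0 therefore cannot count against a delay. The position on the slide cannot be told apart from genotype, and an effect of the genotype, direct or through the health of the embryos, stays open and untested.

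The second pattern is the fall of first arch genes such as Lhx8, Hand2 and Barx1. An equal loss of all arch mesenchyme from the null pools would lower arch genes alike, but the SD between the log2 differences of 16 arch mesenchyme genes was 1.07, against 0.10 to 0.72 (95% range) in 10000 resamples of the residuals. This set holds all 8 genes of the arch list that fell and leaves out the 4 that rose, Msx2, Alx4, Edn1 and Ednra; over all 25 genes of the list the SD was 1.17 against 0.10 to 0.61, and Dlx5 (-0.25 ± 0.14), Dlx6 (-0.28 ± 0.17) and Prrx2 (-0.29 ± 0.19) did not pass. Genes also expressed outside the arch would fall less, and probes of Lhx6 (-0.08 and -1.69) and Prrx1 (-0.85 and 0.68) disagree, so a partial loss of some arch cells stays open. Fewer neural crest cells in the null heads would lower crest genes, whose mean difference was 0.41 (95% interval 0.32 to 0.51); this speaks against an overall loss, though these genes are also active in other head tissue, Sox10 (0.35 ± 0.29) and Foxd3 (0.25 ± 0.16) did not pass, and a loss in the arch alone stays open, as does an untested change of regulation by genotype.

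The third pattern is the rise of Hoxb5, Hoxb7, Hoxb8 and Tbx6. Trunk tissue in the null pools could bring these genes, and the mean difference of 5 somite genes was -0.22 (95% interval -0.54 to 0.09), with baseline levels in wild type heads that could hide a small share, so it stays open. This set holds Meox1, which fell (-0.91), and leaves out Pax7, which rose (0.85). Hoxb6 (-0.27 ± 0.47), Hoxa7 (-0.16 ± 0.29) and Hoxa9 (-0.27 ± 0.39), which trunk tissue would also bring, did not pass, which does not rule out a small share. The background correction of dim spots could also produce it: after normexp on the median signal 2 of the 4 genes were still called, Hoxb8 (3.35 ± 0.70 before and 0.67 ± 0.17 after) and Tbx6 (1.90 ± 0.15 and 1.35 ± 0.14). Hoxb5 (2.74 ± 0.59 and 0.31 ± 0.15) and Hoxb7 (2.29 ± 0.48 and 0.057 ± 0.19) were not, as their differences shrank. The second probe of Tbx6 differed by 0.08. A genotype effect on these genes is untested beyond this.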

How the results depend on the processing

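Normexp, the neighbour counts and their directions, and the counts that weigh the filter on dim probes were chosen after seeing the data. The normexp offset of 50 draws the differences of dim genes toward 0 by construction. Of 131 named genes that changed, 82 kept their call in every setting tried and none changed sign; 59 of 1422 values under the alternatives and 132 of 786 with 1 array left out no longer passed, and 20 genes were not called with normexp, which moved 42 of the named calls by over 1.5-fold, each toward 0. The count of 3503 was 2959 to 4915 under normexp, the scalings, the probe rules and other thresholds, with 45.4% to 58.5% of calls higher and a median over all tested genes of -0.093 to 0.028 across normexp, the other scalings and the deposited table; 51 calls changed sign with normexp and 16 with the mean of a gene's probes, none among named genes. Without the filter on dim probes 2269 genes changed, 1034 lower, and Arid3b (-1.19) lost its call. More tests alone gave 3054 calls among the 14902 shared genes, and the p-values of the fit without the filter, adjusted over these genes alone, gave 2594. Array weights called 6681 genes, 3228 higher and 3453 lower, but 5 lists; the cause was not tested. An estimated correlation called 0 lists (4 at an unadjusted p under 0.05) and fry 17, which asks another question. With 1 array left out, genes changed ran from 1513 to 5197, genes higher from 876 to 2535, genes lower from 637 to 2662, lists from 5 to 12 and Arid3b from -1.42 to -0.87; fewer arrays lower most counts, and the rise without wild type replicate 3 has no tested cause. With the replicate block, which is the slide block, 3689 genes and 10 lists were called. Of 131 named genes 129 kept their call, and Wnt6 and Lin28a did not. Isl1, Fgf3 and Myl3 gained a call. Same-numbered arrays deviated together in 2 of 3 pairs (correlations of -0.20, 0.15 and 0.42), and wild type replicate 1 correlated best with null replicate 2 (0.49). Of the 9 called lists, 6 of 90 values under alternatives and 9 of 54 with an array left out lost the call, for the Bmp, cranial mesenchyme, neural progenitor and neuronal lists. The planned normexp on mean signals and the windows by distance around Arid3b were not run; 10 or 50 genes on each side gave 5 of 20 (5 higher, 0 lower) and 20 of 100 (16 higher, 4 lower) changed, with exact p of 0.0637 and 0.0134 for the directions. The medians of 15 lists that were not called, and of 0 called ones, changed sign in at least 1 setting. Signal near background limits the genes given as bounds.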

Other observations

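All 8 gene groups in this part were chosen after the data were examined, some of them from genes already seen to change, so their tests describe these arrays and are not independent evidence. Genes of the circadian clock and its output were mostly higher in null heads: 13 of 19 rose and 1 fell. Dbp, an output gene of the clock, rose by 2.25 ± 0.12, Rora by 2.84 ± 0.33, Bhlhe41, well above background on 2 of 3 wild type arrays, by 2.19 ± 0.27 (4.39 on its other probe) and Nr1d1, a repressor of the clock, by 1.60 ± 0.30, while Arntl, the activator also known as Bmal1, was the member that fell (-1.34 ± 0.16; list median 1.16, with 1.04, 1.16 and 0.88 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 4.30e-07, and adjusted p = 0.0357 with an estimated correlation). Genes of glycogen metabolism rose in 7 of 16 cases and fell in none, with the glycogen-targeting phosphatase subunit Ppp1r3c at 2.94 ± 0.17, the liver phosphorylase Pygl at 2.13 ± 0.13 and the synthase Gys1 at 1.24 ± 0.23 (list median 0.48, with 0.41, 0.65 and 0.79 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 6.09e-05, and adjusted p = 0.11 with an estimated correlation).

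Regulators of the pituitary and hypothalamus fell in 10 of 15 cases and rose in none: Lhx3 at -2.20 ± 0.16, Gsx1 at -2.09 ± 0.21 and Hesx1 at -1.18 ± 0.22 (list median -1.10, with -1.14, -1.10 and -0.93 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 2.41e-06, and adjusted p = 0.135 with an estimated correlation). Of 10 lens crystallin genes 4 fell, Crygf among them (-2.44 ± 0.24), and none rose; Crygf was well above background on 2 of 3 null arrays and its other probe differed by -0.10 (list median -0.71, with -0.80, -0.97 and -0.68 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 3.79e-04, and adjusted p = 0.11 with an estimated correlation). Of 37 proteasome subunits 12 fell and none rose (list median -0.52, with -0.79, -0.50 and -0.43 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 4.30e-07, and adjusted p = 0.11 with an estimated correlation). Of 78 respiratory chain genes 8 fell and 3 rose (list median -0.41, with -0.79, -0.22 and -0.16 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 2.70e-04, and adjusted p = 0.599 with an estimated correlation). The 80 ribosomal protein genes gave 1 rise and no fall (list median 0.03, with -0.26, 0.24 and 0.12 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 0.530, and adjusted p = 0.922 with an estimated correlation), and the 17 aminoacyl-tRNA synthetase genes 4 rises and 1 fall (list median 0.21, with 0.23, 0.30 and 0.18 within slides 1, 2 and 3; camera adjusted p over these 8 lists of 0.0558, and adjusted p = 0.135 with an estimated correlation).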
